A study of Mus musculus with 28 samples.

How the data were processed

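Gene expression arrays were analysed from 14 Emu-myc lymphomas transduced with Bcl2, each with 1 untreated and 1 ADR-treated culture (0.05 µg/ml, 5 days), 28 arrays in all. The deposited values are log2 expression values for 45101 probe sets per array. Per the submitters' processing notes, the arrays were processed with RMA and Partek 6.5; RMA corrects background, normalizes between arrays and summarises the probes of a probe set. The genome build was not given in the sources used here, and no coordinates are printed. The labels name no sort or gate that would part lymphoma cells from the irradiated feeder cells before RNA was extracted.

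Probe sets were assigned to genes with the annotation supplied for the array, dated 2016. Of the probe sets, 34945 had 1 gene, 932 had several, 9160 had no gene listed and 64 were controls; the last 3 kinds were left out of the gene tests. Of the probe sets with 1 gene, 34741 had an Entrez identifier in the RefSeq table. For the 9009 genes with more than 1 probe set the probe set with the highest mean over the 28 arrays was used, which left 18193 genes. All value columns were mapped to a sample.

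The pairing comes from the labels, which give the lymphoma of each array. It was checked on the arrays as the correlation of deviations from the group means. Arrays of the same lymphoma correlated at r from 0.27 to 0.61 (median 0.48), against a median of -0.08 for arrays of different lymphomas. In 12 of 14 lymphomas the partner was the best match, the exceptions being 2949 and 6054. Xist, expressed from the inactive X chromosome, was high in both arrays of 9 lymphomas (at least 10.9) and low in both arrays of 5 (at most 5.57). Y-linked genes, set for the same check, did not match in every pair. In lymphoma 9584 Eif2s3y went from 4.74 to 8.61, while Kdm5d stood at 7.17 and 7.20.

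Array quality was compared within pairs by exact sign-flip tests. The 3' minus 5' signal of actin was 0.43 ± 0.19 (SD) in untreated and 0.41 ± 0.24 in ADR arrays (exact p = 0.820, n = 14 pairs), and that of Gapdh 0.03 ± 0.03 and 0.12 ± 0.25 (exact p = 0.226). The ADR array of lymphoma 1570 stood apart, at 0.92 for actin and 0.92 for Gapdh, where the next highest Gapdh value was 0.38 in the ADR array of 6054. The median log2 value of an array was 4.73 and 4.75 (exact p = 0.0192). For arrays the precision is limited by the number of arrays and by signal over background, since genes near the low end of the scale have compressed changes.

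Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with lymphoma as a block, and p-values were adjusted by Benjamini-Hochberg over all genes at a threshold of 0.05. Standard errors are those of the moderated fit. Of 35 gene lists with 815 members written down, 765 members were measured. Lists were tested by camera with a preset inter-gene correlation of 0.01 and adjusted over the 35 lists, and again with a correlation estimated per list. They were also tested by fry and by an exact sign-flip test. The latter enumerated 16384 flips of the 14 list changes (smallest possible p 1.22e-04). Camera asks whether a list changed more than other genes, while fry and the sign-flip test ask whether it changed at all. Differences between the 11 lymphomas described as samples of an earlier series and the other 3 were tested by limma on the 14 per-lymphoma changes, and for list means by an exact permutation over 364 splits (smallest possible p 0.00275). Correlations across lymphomas are Pearson r and Spearman rho with 100000 permutations, adjusted within families of 7 relations for the G2/M list and 34 for the fibroblast list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

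Groups, tests, gene lists and the rule for naming genes were set before the data were examined. The rule named the 10 largest rises and the 10 largest falls among genes past the threshold in the same direction in all 14 lymphomas, 13 genes in any case (11 of 13 are reported), up to 3 members per list with the largest change, and the 5 genes with the smallest p for the difference between the 11 and the 3 lymphomas. Some list examples were left out for length, and genes outside the rule are marked as chosen after their values were seen. Fits with the fibroblast change as a covariate, fits without lymphomas 403 and 5560, the sign-flip tests and the correlations with the fibroblast and macrophage lists were chosen after the data were seen. In the covariate fit, a value at no fibroblast change is the intercept of a gene's 14 changes regressed on the change of the fibroblast list mean. Camera was run in that fit with the preset correlation only.

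The paired fit was tested on simulated data with 200 changed genes among 18193. It recovered 74.6%, 89.6% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale, with 8 false among 184 calls. For a difference between 3 and 11 lymphomas it recovered 7.46%, 61.2% and 89.4% of the same sizes. Alternatives tried were no replicate block or a random one, other choices of probe set, leaving out the 40% of genes with the lowest mean, centring arrays on their median, quantile normalization, a trended and robust variance model, array weights, each part of the samples alone, and leaving out each lymphoma in turn.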

Results

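Gene expression was measured in primary B-cell lymphomas of Emu-myc transgenic mice, in which the Myc oncogene is expressed throughout the B-cell lineage and aggressive lymphomas arise. The lymphoma cells came from lymph nodes of C57BL/6 mice and had been transduced with Bcl2, an inhibitor of apoptosis. Blocking apoptosis is meant to let DNA damage lead to senescence rather than cell death, and senescence itself was not tested here. They were cultured on irradiated NIH 3T3 cells, a mouse fibroblast line that served as a feeder layer. Each of 14 lymphomas contributed 1 untreated culture and 1 culture treated for 5 days with 0.05 µg/ml Adriamycin (ADR, doxorubicin), a topoisomerase poison that breaks DNA. This gave 28 arrays, 14 per group, and the matched pairs address the transcriptional profile of treatment-induced senescence. The number of arrays limits the precision, and each change below is the ADR value minus the untreated value of the same lymphoma on the log2 scale, with its standard error (SE) over n = 14 pairs unless stated. Labels give each lymphoma its own identifier, and names such as lymphoma 403 are those identifiers. Gene lists named below were fixed before the data were examined.

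After ADR, 37 of 37 measured genes of the G2/M list were lower, and 25 of 38 SASP, 24 of 25 fibroblast and 10 of 15 macrophage genes were higher. Camera called these lists with a preset correlation, and with an estimated correlation none was called, at adjusted p = 0.150, 0.148, 0.159 and 0.152. Among genes that moved the same way in all 14 lymphomas, the largest falls were those of the spindle motor Kif11 (-2.63 ± 0.28), the chromosomal passenger kinase Aurkb (-2.35 ± 0.19), the cyclins Ccnb2 (-2.34 ± 0.25) and Ccna2 (-2.23 ± 0.23), and the proliferation marker Mki67 (-2.19 ± 0.23). Cenpp, Pbk, the checkpoint kinase Bub1b, Cdca2 and the checkpoint kinase Ttk followed, with falls from -2.17 to -2.09. The largest rises were those of the neutrophil chemokine Cxcl5 (3.71 ± 0.65), the serine protease Prss23 (3.20 ± 0.48), the Kit ligand gene Kitl (3.16 ± 0.51), the chromatin protein Hmga2 (3.00 ± 0.39) and Emp1 (3.00 ± 0.43). Grb10, the macrophage-expressed Ms4a6d, the collagen gene Col1a2, the collagenase Mmp13 and the chemokine Cxcl2 followed, with rises from 2.91 to 2.96. The limma adjusted p of these 20 genes lay between 1.73e-06 for Ms4a6d and 4.45e-04 for Cxcl5.

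Of 18193 genes tested, 2790 were higher and 2435 were lower after ADR at an adjusted p of 0.05. Of these, 598 rose and 335 fell by at least 2-fold, and 523 were higher and 471 lower in 14 of 14 lymphomas. Without the 2 lymphomas with the largest rise of fibroblast genes, 403 and 5560, 2457 genes were higher and 2031 lower, of which 2304 and 1926 were also called over all 14. With the change of fibroblast genes as a covariate, 1032 genes were higher and 878 lower at no fibroblast change, and 217 rose and 327 fell by at least 2-fold. Of 115 named genes with a call, 57 kept their direction without a call in that fit and 15 changed sign, of which all but Thy1 were also without a call. Some calls were lost with little change in size and a wider SE. Cdkn1a went from 1.11 to 0.97 ± 0.34 and Atf3 from 1.09 to 1.05 ± 0.33. A lost call in that fit can thus reflect lower precision as well as a smaller value. Cxcl5 stood at 0.10 ± 0.46, Prss23 at 0.55 ± 0.34, Kitl at 0.21 ± 0.24, Emp1 at 0.80 ± 0.42, Grb10 at 0.50 ± 0.30 and Col1a2 at 0.14 ± 0.14, while Hmga2 (0.75 ± 0.17), Ms4a6d (3.49 ± 0.38), Cxcl2 (2.21 ± 0.42) and Kif11 (-2.86 ± 0.51) kept an adjusted p under 0.05. Among the 579 genes at least 2-fold higher and outside the fibroblast list, 45.1% correlated with the fibroblast change at r above 0.7 across the 14 lymphomas, against 7.12% of all genes. Principal component 1 held 33.2% of the variance and was higher in the ADR array of all 14 lymphomas.

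**Figure D1:**
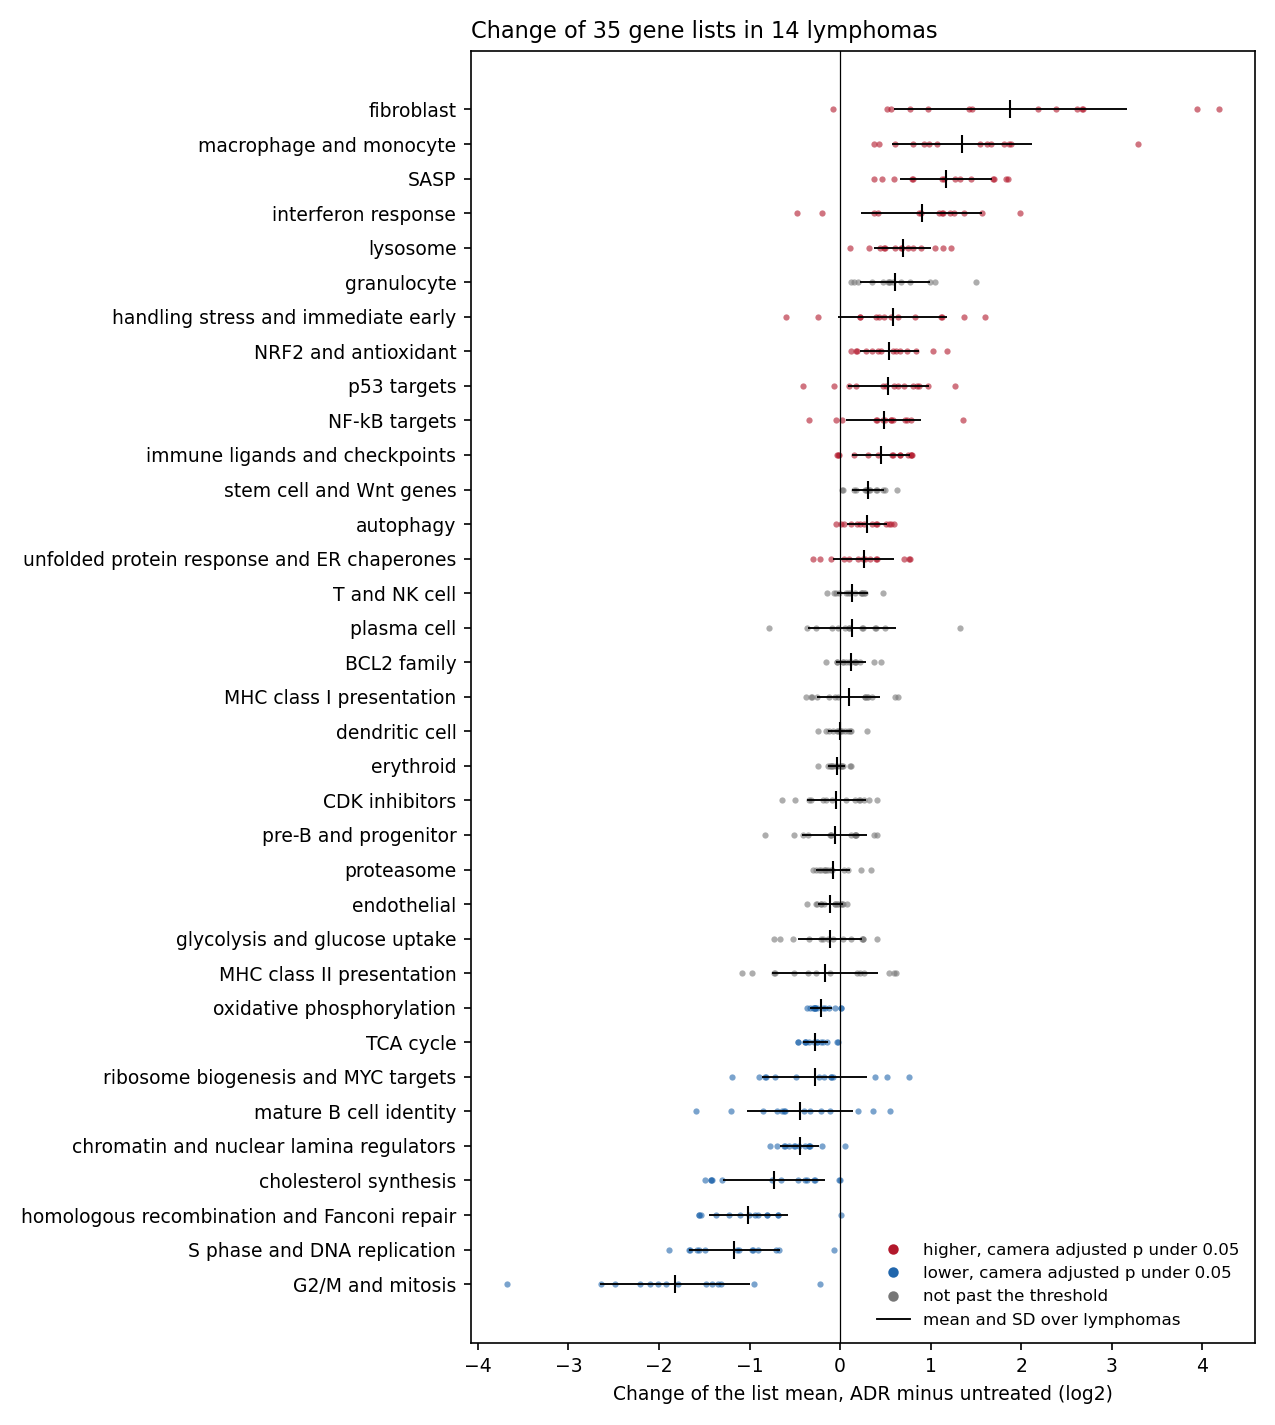
Change of the mean of each of 35 gene lists (x axis, log2, ADR minus untreated), with 1 dot per lymphoma and the mean with its SD over 14 lymphomas as a black bar. Colours give the camera call with a preset correlation, and the lists run from G2/M and mitosis at -1.83 to fibroblast genes at 1.88.

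Replication and mitosis genes fell nearly without exception. All 37 measured members of the G2/M list fell, with a median change of -1.85, as did 37 of 38 genes of S phase and DNA replication, with a median of -1.16. Adjusted over the list alone, 37 of 37 and 38 of 38 fell. Examples of the replication list were the polymerase subunit Pola1 (-1.94 ± 0.22), the thymidine kinase Tk1 (-1.77 ± 0.17) and the origin licensing factor Cdc6 (-1.68 ± 0.21). The decatenating enzyme Top2a fell by 1.93 ± 0.23. Of 32 genes of homologous recombination and Fanconi repair, 30 fell (31 adjusted over the list alone; median -1.06), including Fancd2 (-1.82 ± 0.20), Rad51ap1 (-1.75 ± 0.22) and Brca1 (-1.74 ± 0.22). Camera adjusted p was 5.56e-31 for G2/M, 4.03e-28 for S phase and 2.47e-21 for repair. These were adjusted p = 0.150, 0.148 and 0.148 with an estimated correlation, and the exact sign-flip test over the 14 lymphomas gave adjusted p = 4.27e-04, 4.27e-04 and 6.57e-04. Lymphomas differed in size: the G2/M list changed by -3.68 in 2949 and by -0.22 in 9584. The mean change of the fibroblast list correlated with the G2/M change at r = 0.25 (permutation p = 0.401, adjusted p = 0.676; rho = 0.27, permutation p = 0.358), with -0.0054 without lymphomas 403 and 5560 and 0.55 within the 11 lymphomas of an earlier series.

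Chromatin and nuclear lamina regulators mostly fell, with 13 of 20 members lower and 3 higher (14 lower and 3 higher adjusted over the list alone; median -0.69). Lmnb1, the lamin whose loss is a known senescence marker, fell in all 14 lymphomas (-1.45 ± 0.23, adjusted p = 1.72e-04), as did the chromatin protein Hmgb2 (-1.87 ± 0.20) and the DNA methylation cofactor Uhrf1 (-1.66 ± 0.20). Hmga2 rose by 3.00, and the A-type lamin gene Lmna, chosen after its value was seen, by 1.22 ± 0.23. These rises followed the fibroblast change, at r = 0.97 and 0.75, and Hmga2 kept a call at no fibroblast change (0.75 ± 0.17, adjusted p = 0.0127). The list's camera adjusted p was 4.50e-06, and adjusted p = 0.148 with an estimated correlation. At no fibroblast change the list median was -0.34 (camera adjusted p = 0.00400). Lmnb1 was at -0.56 ± 0.31 at no fibroblast change (adjusted p = 0.311), and its change correlated with the fibroblast change at r = -0.66.

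Among CDK inhibitors, Cdkn1a (p21), which p53 induces, rose from 10.7 to 11.8 in log2 level and was higher in 14 of 14 lymphomas (1.11 ± 0.19, adjusted p = 3.49e-04). At no fibroblast change its value was 0.97 ± 0.34 (adjusted p = 0.0876). Cdkn2a, which encodes p16 and Arf, was near the low end of the array scale at 4.10 in both groups (change -2.51e-04 ± 0.09, adjusted p = 0.999), and Cdkn2b changed by 0.44 ± 0.20 (adjusted p = 0.115). Cdkn2d, encoding p19 of the Ink4 family, fell in 13 of 14 lymphomas (-0.95 ± 0.15, adjusted p = 2.02e-04). Of the 7 list members 1 rose, 1 fell and 5 did not pass, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.541).

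**Figure D2:**
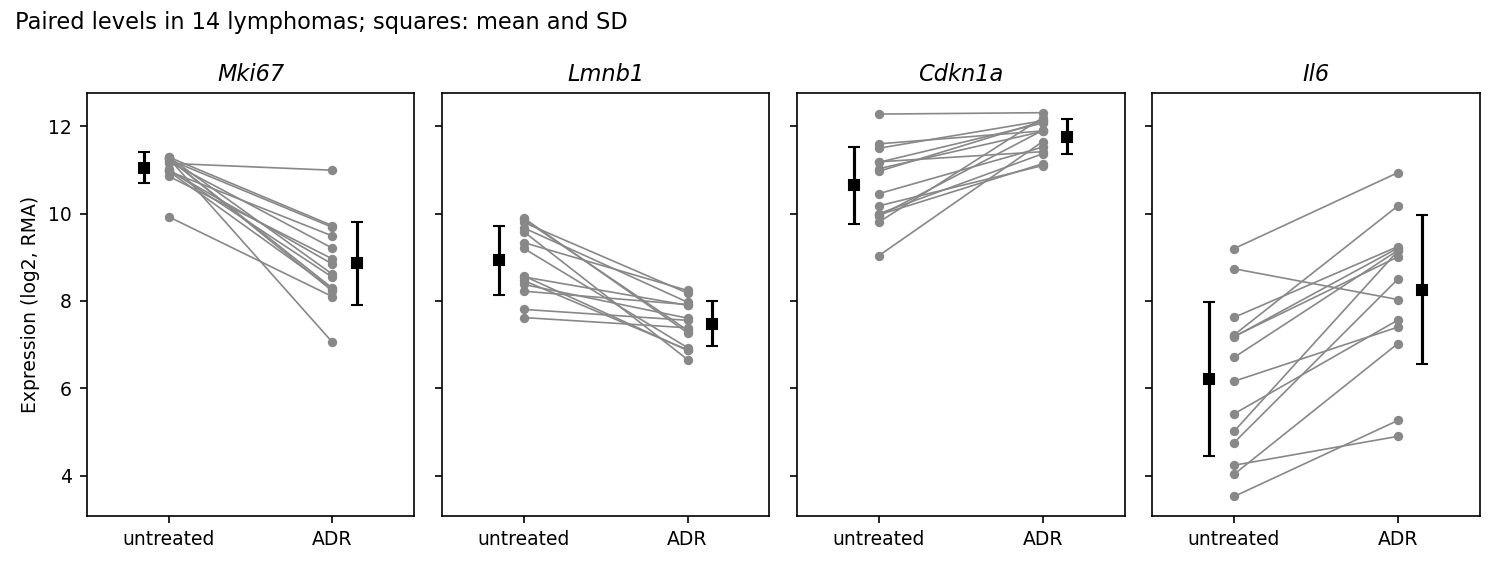
Log2 expression of Mki67, Lmnb1, Cdkn1a and Il6 in untreated and ADR cultures, with 1 grey line per lymphoma (14 pairs) and black squares with bars for the mean and SD of each group. Mki67 and Lmnb1 fell and Cdkn1a rose in all 14 pairs, and Il6 was higher in 13 of 14.

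Targets of p53 rose as a group: 18 of 30 measured members were higher and 2 lower (23 and 4 adjusted over the list alone; median 0.51, camera adjusted p = 5.61e-06). With an estimated correlation this was adjusted p = 0.228, and by exact sign-flip adjusted p = 0.00247. Phlda3, an inhibitor of Akt, rose by 1.66 ± 0.24, the kinase gene Plk2 by 1.39 ± 0.33 and the receptor gene Eda2r by 1.26 ± 0.24. Among members chosen after their values were seen, the p53 inhibitor gene Mdm2 rose by 1.22 ± 0.20 and Ccng1 by 0.87 ± 0.13, each in 13 of 14 lymphomas, and the damage sensor Ddb2 fell by 1.11 ± 0.24. At no fibroblast change the list median was 0.47 (camera adjusted p = 0.00296) and the fitted list mean 0.38 ± 0.22. The list change correlated with the fibroblast change at r = 0.23 (permutation p = 0.429, adjusted p = 0.676). Among members, values at no fibroblast change were 1.16 ± 0.42 for Phlda3 (adjusted p = 0.0945) and 0.39 ± 0.53 for Plk2 (adjusted p = 0.739). Eda2r, which followed the fibroblast change (r = 0.83), was at 0.04 ± 0.25. The list mean changed by -0.41 in lymphoma 2949 and by -0.07 in 6054, against 1.27 in 1570, whose ADR array had the highest 3' minus 5' signal of actin and Gapdh, and 0.97 in 9583.

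Myc fell in 12 of 14 lymphomas (-0.71 ± 0.18, adjusted p = 0.00734), and its change correlated with the fibroblast change at r = -0.82, with 0.16 ± 0.20 at no fibroblast change. Bcl2 fell in all 14 by its brightest probe set (-0.90 ± 0.15, adjusted p = 3.67e-04). It was 1 of 5 Bcl2 probe sets to pass, and the probe set with the largest variance read 0.19 (adjusted p = 0.429). Whether the Myc and Bcl2 probe sets also read the Myc transgene or the transduced Bcl2 was not tested. In the BCL2 family list, 3 members rose and 1 fell of 14 (5 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.236). The survival genes Bcl2l1 (1.00 ± 0.16) and Mcl1 (0.38 ± 0.07) rose, each in 13 of 14 lymphomas. Bcl2 was at -0.60 ± 0.27, Bcl2l1 at 0.29 ± 0.19 and Mcl1 at 0.30 ± 0.14 at no fibroblast change, each without a call (adjusted p = 0.176, 0.403 and 0.185). Glb1, which encodes the lysosomal beta-galactosidase used as a senescence stain, rose by 0.38 ± 0.11 in 13 of 14 (adjusted p = 0.0171), and stood at 0.17 ± 0.20 at no fibroblast change. Of the 13 genes set to be always reported, 11 are given here, including the receptor Kit at 0.02 ± 0.05 (adjusted p = 0.831).

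Genes of the senescence-associated secretory phenotype (SASP) rose: 25 of 38 measured members were higher and 0 lower, with the same count adjusted over the list alone and a median of 1.22. The matrix protease Mmp13 (2.92 ± 0.41), the chemokine Cxcl2 (2.91 ± 0.26) and Ccl2 (2.86 ± 0.38), which attracts monocytes, rose in 14 of 14 lymphomas. The interleukin Il6 (2.04 ± 0.30, adjusted p = 1.03e-04, 13 of 14 lymphomas) rose by less. Values at no fibroblast change were 1.33 ± 0.52 for Ccl2, 2.13 ± 0.70 for Mmp13 and 1.69 ± 0.54 for Il6, with adjusted p = 0.126, 0.0656 and 0.0570. Camera adjusted p was 2.87e-12, adjusted p = 0.148 with an estimated correlation, and the exact sign-flip test gave adjusted p = 4.27e-04. The list changed from 0.37 to 1.86 between lymphomas, and this followed the fibroblast change. Pearson r was 0.82 (permutation p = 3.20e-04, adjusted p = 0.00181) and Spearman rho 0.83 (permutation p = 4.30e-04, adjusted p = 0.00449) over 34 lists tested. It was 0.77 without the lymphomas 403 and 5560, which lay farthest from the median, and 0.89 within the 11 lymphomas of an earlier series. At no fibroblast change the list median was 0.35 (camera adjusted p = 0.00358), with 7 of 38 members higher. Macrophage genes rose beside it, with r = 0.25 between both changes (permutation p = 0.400), and -0.19 without lymphomas 2581 and 2949.

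Interferon-response genes rose in 25 of 32 cases and fell in 0 (26 adjusted over the list alone; median 0.78, camera adjusted p = 8.36e-11). This was adjusted p = 0.189 with an estimated correlation and 0.00190 by exact sign-flip. The antiviral gene Ifit1 rose by 2.17 ± 0.29 in 14 of 14 lymphomas, the chaperone gene Rtp4 by 2.09 ± 0.36 and the ISG15 protease Usp18 by 2.09 ± 0.37, each of the latter in 12 of 14. The list mean went down in lymphomas 403 (-0.48) and 2949 (-0.20) and up in the other 12. Its correlation with the fibroblast change was r = -0.14 (permutation p = 0.645, adjusted p = 0.830) and turned to 0.36 without lymphomas 403 and 5560. With the macrophage change r was 0.49 (permutation p = 0.0767, adjusted p = 0.373), and 0.59 within the earlier 11. NF-kB targets rose in 9 of 20 cases and fell in 0 (11 adjusted over the list alone; median 0.45, camera adjusted p = 4.72e-05). With an estimated correlation this was adjusted p = 0.189, and at no fibroblast change the median was 0.22 (camera adjusted p = 0.112). The NF-kB change correlated with the fibroblast change at r = 0.35 (permutation p = 0.227, adjusted p = 0.482), and at 0.75 without lymphomas 403 and 5560. The signalling adaptor Traf1 rose by 1.18 ± 0.21 in 12 of 14.

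Immune ligands and checkpoints rose in 6 of 15 cases and fell in 0 (7 adjusted over the list alone; median 0.33, camera adjusted p = 0.00491). This was adjusted p = 0.152 with an estimated correlation, and the median was 0.17 at no fibroblast change (camera adjusted p = 0.112). The costimulatory ligand Cd80 rose by 1.38 ± 0.18 in all 14 lymphomas and the inhibitory ligand Cd274 (PD-L1) by 1.31 ± 0.22 in 13. Cd274 was at 0.49 ± 0.32 at no fibroblast change. Antigen presentation lists were not called. Of 12 MHC class I genes 4 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.564), and of 11 class II genes 1 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.536). H2-D1, a class I heavy chain with near-identical relatives, rose by 0.51 ± 0.15, with -0.06 ± 0.20 at no fibroblast change. The class II peptide-loading regulator H2-Ob fell by 1.17 ± 0.27, with -0.17 ± 0.38 at no fibroblast change, and the protease gene Ctss rose by 0.67 ± 0.14, with 0.30 ± 0.24 at no fibroblast change (adjusted p = 0.513).

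Lysosomal genes rose in 30 of 36 cases and fell in 0, with the same count adjusted over the list alone and a median of 0.65 (camera adjusted p = 2.62e-16). This was adjusted p = 0.148 with an estimated correlation and 4.27e-04 by exact sign-flip. The protease genes Ctsd (1.76 ± 0.18) and Ctsl (1.60 ± 0.29) and the proton pump subunit Atp6v0a1 (1.38 ± 0.09) rose in 14 of 14 lymphomas. Ctsl was at 0.49 ± 0.41 at no fibroblast change, Ctsd at 1.18 ± 0.29. The list change went with the fibroblast change at r = 0.61 (permutation p = 0.0193, adjusted p = 0.0597) and rho = 0.70 (permutation p = 0.00660, adjusted p = 0.0321), with r = 0.86 without lymphomas 403 and 5560 and 0.56 within the earlier 11. Its median was 0.36 at no fibroblast change (camera adjusted p = 5.13e-07). With the macrophage change r was 0.54 (permutation p = 0.0425, adjusted p = 0.373) and rho 0.40 (permutation p = 0.154), with r = 0.21 without lymphomas 2581 and 2949 and 0.62 within the earlier 11. Autophagy genes rose in 18 of 32 cases and fell in 3 (19 and 3 adjusted over the list alone; median 0.25, camera adjusted p = 3.16e-05, and adjusted p = 0.152 with an estimated correlation). The autophagy receptor Sqstm1 (p62) rose by 1.21 ± 0.12 in all 14. The autophagy change correlated with the fibroblast change (r = 0.83, permutation p = 2.60e-04, adjusted p = 0.00181; rho = 0.90, adjusted p = 6.80e-04; 0.86 without 403 and 5560 and 0.80 within the earlier 11), and its median was 0.07 at no fibroblast change (camera adjusted p = 0.431).

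Of 31 unfolded protein response genes, 11 rose and 0 fell (the same adjusted over the list alone; median 0.16, camera adjusted p = 0.00215, and adjusted p = 0.429 with an estimated correlation). The list median was 0.21 at no fibroblast change, no smaller than in the paired fit (camera adjusted p = 0.0714). The chaperone cofactor Dnajb9 rose by 0.69 ± 0.09 and the transcription factor gene Atf3 by 1.09 ± 0.18, both in 14 of 14 lymphomas, with Atf3 at 1.05 ± 0.33 at no fibroblast change (adjusted p = 0.0550). Of 16 NRF2 and antioxidant genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.54, camera adjusted p = 6.41e-04). With an estimated correlation this was adjusted p = 0.152, and its change followed the fibroblast change (r = 0.67, permutation p = 0.00977, adjusted p = 0.0369; rho = 0.66, adjusted p = 0.0451; 0.58 without 403 and 5560). At no fibroblast change its median was 0.25 (camera adjusted p = 0.227). The redox gene Srxn1 rose by 1.40 ± 0.21, with 0.40 ± 0.22 at no fibroblast change, and Hmox1, which degrades haem, by 1.08 ± 0.33 in 12 of 14, with 1.20 ± 0.60 at no fibroblast change (adjusted p = 0.242). Proteasome genes rose in 1 and fell in 8 of 31 cases (1 and 9 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0575). Its change went against the fibroblast change at r = -0.66 (permutation p = 0.00943, adjusted p = 0.0369) and rho = -0.62 (adjusted p = 0.0687). Without lymphoma 5043 the proteasome list was at adjusted p = 0.00728, without 2949 at 0.0199, without 9584 at 0.0366 and without 1467 at 0.0407.

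Metabolic genes fell in part. Cholesterol synthesis genes were lower in 13 of 20 cases and higher in 0 (17 lower adjusted over the list alone; median -0.65, camera adjusted p = 5.47e-09, and adjusted p = 0.189 with an estimated correlation). The lipid transfer gene Stard4 (-1.52 ± 0.18), the isomerase gene Idi1 (-1.39 ± 0.27) and the farnesyl diphosphate synthase Fdps (-1.37 ± 0.22) fell most. Idi1 was at -0.71 ± 0.44 (adjusted p = 0.377) and Fdps at -1.20 ± 0.41 (adjusted p = 0.0734) at no fibroblast change. TCA cycle genes were lower in 13 of 22 cases and higher in 0 (14 lower adjusted over the list alone; median -0.23, camera adjusted p = 2.01e-06). Oxidative phosphorylation genes were lower in 20 of 32 and higher in 0 (22 lower adjusted over the list alone; median -0.21, camera adjusted p = 4.08e-08). Both lists were at adjusted p = 0.152 with an estimated correlation. At no fibroblast change the TCA median was -0.11 (camera adjusted p = 0.00644) and that of oxidative phosphorylation -0.17 (camera adjusted p = 3.95e-04), and the TCA change went with the fibroblast change at r = -0.51 (permutation p = 0.0626, adjusted p = 0.164). The fumarase gene Fh1 (-0.78 ± 0.08), Idh2 (-0.71 ± 0.10) and the complex III subunit Uqcrfs1 (-0.56 ± 0.06) fell in all 14 lymphomas. Glycolysis genes went both ways, with 4 of 22 higher and 5 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.187). Aldoc fell by 1.36 ± 0.21 and Pfkp by 0.74 ± 0.12, while Eno2 rose by 1.06 (limma adjusted p = 0.0152). At no fibroblast change Eno2 was at -0.58 ± 0.25 and the glycolysis median was -0.44 (camera adjusted p = 3.19e-05). The glycolysis change went with the fibroblast change at r = 0.65 (permutation p = 0.0126, adjusted p = 0.0429) and rho = 0.62 (adjusted p = 0.0671).

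Genes of ribosome biogenesis, which MYC drives, were lower in 9 of 38 cases and higher in 0, with the same count adjusted over the list alone (median -0.25, camera adjusted p = 1.40e-04). This was adjusted p = 0.585 with an estimated correlation and adjusted p = 0.123 by exact sign-flip. The nucleolar factor Tcof1 fell by 0.62 ± 0.10 in 13 of 14 lymphomas, with -0.17 ± 0.12 at no fibroblast change. The list went down where fibroblast genes went up (r = -0.86, permutation p = 7.00e-05, adjusted p = 0.00181; rho = -0.81, adjusted p = 0.00449; -0.83 without 403 and 5560 and -0.86 within the earlier 11). At no fibroblast change its median was 0.48 in the opposite direction (camera adjusted p = 6.55e-09 with the preset correlation). The members moved together, with an estimated correlation of 0.82 in the paired fit, so that p overstates the evidence. The fitted list mean at no fibroblast change was 0.44 ± 0.15.

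Markers of other cell types changed with ADR. Fibroblast genes rose in 24 of 25 cases and fell in 0 (24 adjusted over the list alone; median 1.89, camera adjusted p = 2.87e-12, adjusted p = 0.159 with an estimated correlation, and exact sign-flip adjusted p = 6.57e-04). The matrix genes Ccn2 (3.23 ± 0.52), Fn1 (3.18 ± 0.54) and Bgn (3.12 ± 0.53) rose in 13 of 14 lymphomas. They were at 0.27 ± 0.33, 0.23 ± 0.40 and 0.18 ± 0.37 at no change of their list. As list members they are part of that covariate, so such small values are largely built in. The fibroblast list mean changed by 4.19 in lymphoma 403, 3.94 in 5560 and -0.08 in 1467, and its SD over lymphomas was 1.29. Macrophage and monocyte genes rose in 10 of 15 cases and fell in 0 (10 higher and 1 lower adjusted over the list alone; median 1.48, camera adjusted p = 2.01e-06, and adjusted p = 0.152 with an estimated correlation). Ms4a7 (2.70 ± 0.30), Adgre1 (2.21 ± 0.26) and the lipopolysaccharide receptor Cd14 (2.11 ± 0.22) rose in 14 of 14, and the fibroblast and macrophage changes correlated at r = -0.03 (permutation p = 0.924), and at 0.36 without 403 and 5560. Granulocyte genes rose in 3 of 9 cases and fell in 0, with the same count adjusted over the list alone, among them Mmp8 (2.51 ± 0.39) and S100a8 (2.08 ± 0.41), while the list was not called (camera adjusted p = 0.165, median 0.04). Mmp8 was at 1.90 ± 0.69 (adjusted p = 0.0950) and S100a8 at 1.06 ± 0.68 (adjusted p = 0.396) at no fibroblast change.

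Mature B cell genes were lower in 10 of 24 cases and higher in 1, with the same count adjusted over the list alone (median -0.35, camera adjusted p = 0.00491, and adjusted p = 0.429 with an estimated correlation). The inhibitory coreceptor Cd22 fell in 14 of 14 lymphomas (-1.37 ± 0.15) and stood at -0.92 ± 0.24 at no fibroblast change. Vpreb3 fell by 1.93 ± 0.38 in 13, with -0.10 ± 0.41 at no fibroblast change. The B cell list went down where fibroblast genes went up (r = -0.83, permutation p = 2.30e-04, adjusted p = 0.00181; rho = -0.78, permutation p = 0.00132, adjusted p = 0.00748). It was -0.69 without lymphomas 403 and 5560, -0.84 within the earlier 11, and the list median was 0.32 at no fibroblast change (camera adjusted p = 0.184). Pre-B and progenitor genes went both ways, with 2 of 13 higher and 2 lower (the same adjusted over the list alone; camera adjusted p = 0.613), the interleukin receptor Il7r rising by 0.90 ± 0.26 and the receptor Flt3 falling by 0.47 ± 0.12. These were at 0.37 ± 0.45 (adjusted p = 0.701) and -0.64 ± 0.21 (adjusted p = 0.0620) at no fibroblast change. Of 13 plasma cell genes 2 rose and 0 fell (1 adjusted over the list alone), with a median of -0.03, a mean of 0.13 and an upward camera direction (adjusted p = 0.539). The secretory regulator Xbp1 rose by 0.54 ± 0.14, with 0.63 ± 0.26 at no fibroblast change (adjusted p = 0.149).

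Stem cell, dendritic, T and NK, endothelial and erythroid lists were not called by camera. Of 28 stem cell and Wnt genes 8 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.109). Klf4 rose by 2.62 ± 0.39 and the fibroblast-expressed Cd34 by 2.56 ± 0.47, each in 13 of 14 lymphomas. Klf4 and Cd34 tracked the fibroblast change at r = 0.81 and 0.99, with 0.73 ± 0.42 (adjusted p = 0.324) and -0.26 ± 0.12 at no fibroblast change, and the list did so at r = 0.74 (permutation p = 0.00239, adjusted p = 0.0116; rho = 0.67, adjusted p = 0.0422; 0.57 without 403 and 5560). Of 7 dendritic cell genes 1 rose and 1 fell, with the same count adjusted over the list alone (camera adjusted p = 0.799). Of 15 T and NK cell genes 1 rose and 1 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.536), and that list followed the fibroblast change at r = 0.82 (permutation p = 2.90e-04, adjusted p = 0.00181; rho = 0.82, adjusted p = 0.00449; 0.75 without 403 and 5560). Its riser Thy1, also a fibroblast surface protein, was at 1.48 ± 0.43 and at -1.01 ± 0.22 at no fibroblast change. Of 9 endothelial genes 0 rose and 3 fell, with the same count adjusted over the list alone (camera adjusted p = 0.420), including Egfl7 at -1.09 ± 0.17, with -0.91 ± 0.30 at no fibroblast change (adjusted p = 0.0652). Of 7 erythroid genes 0 passed either way, also adjusted over the list alone (camera adjusted p = 0.536). Handling stress and immediate early genes rose in 4 of 14 cases and fell in 0 (5 adjusted over the list alone; median 0.47, camera adjusted p = 0.0111, and adjusted p = 0.234 with an estimated correlation). The phosphatase gene Dusp1 rose by 1.32 ± 0.27, with 0.13 ± 0.33 at no fibroblast change, and the list followed the fibroblast change at r = 0.82 (permutation p = 3.20e-04, adjusted p = 0.00181; rho = 0.83, adjusted p = 0.00449; 0.85 without 403 and 5560).

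**Figure D3:**
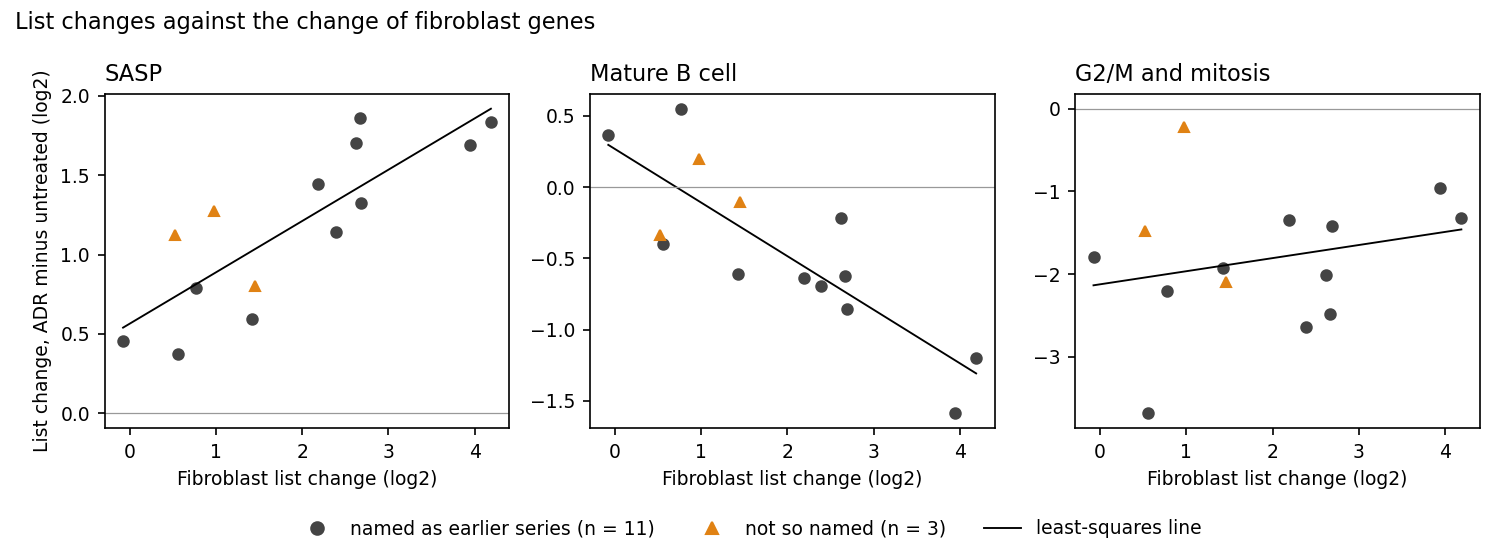
Change of the SASP, mature B cell and G2/M lists (y axes, log2, ADR minus untreated) against the change of the fibroblast list (x axis, log2), 1 point per lymphoma, with least-squares lines. Circles are the 11 lymphomas of an earlier series and triangles the other 3, and r is 0.82, -0.83 and 0.25 from left to right.

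Across lymphomas, the G2/M change was set against the change of 7 other lists, to ask whether lymphomas whose mitotic genes fell further also changed more elsewhere. Changes keep their sign, so a negative r means that a further G2/M fall went with a higher change of the other list. A positive r means that it went with a lower one. None of the 7 relations passed a Benjamini-Hochberg adjustment over all 14 lymphomas, and 1 passed within the earlier 11, the G2/M change against ribosome biogenesis and MYC targets (r = -0.75, permutation adjusted p = 0.0465). The strongest, with the unfolded protein response list, had r = -0.60 (permutation p = 0.0233, adjusted p = 0.163) and rho = -0.47 (permutation p = 0.0934), and r was -0.22 without lymphomas 2949 and 9584. For SASP r was 0.43 (permutation p = 0.122, adjusted p = 0.285) and rho 0.37 (permutation p = 0.192), with 0.25 without the same lymphomas and 0.50 within the earlier 11. For ribosome biogenesis r was -0.50 (permutation p = 0.0635) and rho -0.59 (permutation p = 0.0285), with -0.42 without the same lymphomas.

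Descriptions mark 11 lymphomas as samples of an earlier series and leave 3 unmarked (5043, 9583 and 9584), the only split of the samples in the labels besides treatment. The transporter gene Slc47a1 was the only gene by limma whose ADR change differed between them at an adjusted p of 0.05 (adjusted p = 0.00589), and 999 of 18193 genes were at an unadjusted p under 0.05. It changed by -0.01 ± 0.33 (SD) in the 11 and by -1.85 ± 0.34 (SD) in the 3, a difference of -1.84 ± 0.21. Without 9583 its adjusted p was 0.151 and without 9584 it was 0.0692. None of the 35 lists was called as different between them (exact permutation over 364 splits, smallest adjusted p = 0.429), and 29 lists had the same sign in both. The smallest possible p of this permutation is 0.00275, so a single list could not pass after adjustment over 35 lists. The test thus cannot show that the 11 and the 3 respond alike. Within the 11 alone 2534 genes were higher and 2250 lower, and within the 3 alone 1 and 0.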

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

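Comparisons of real and other splits and of the 11 with the 3 lymphomas were set beforehand; tests of fibroblast and macrophage RNA and of the lymphoma cell share were chosen only after the result was seen.

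A difference between groups drew attention to the transporter gene Slc47a1. Its ADR change in lymphomas 5043, 9583 and 9584 minus that in the 11 lymphomas of an earlier series was -1.84 on the log2 scale (adjusted p = 0.00589; 0.151 without 9583 and 0.0692 without 9584). Its untreated level was 5.04, 6.29 and 4.86 in those lymphomas and from 2.87 to 4.21 in the others, so the fall starts from a higher level. Of 100 splits of the 14 lymphomas into 3 and 11, 13 gave at least as many genes as the 1 found, with a highest other count of 13, so chance is not excluded. That highest split set apart lymphomas 403, 5560 and 9584, whose fibroblast lists changed by 4.19, 3.94 and 0.97, and what these share was not tested. No biological explanation was tested.

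Signals also appeared in probe sets that the gene tests did not use. Of 9160 probe sets with no gene listed, 183 were higher and 324 lower after ADR. Of 932 probe sets listed for several genes, 130 were higher and 158 lower. Which transcripts these are was not analysed here.

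Treatment counts were set against 100 splits that exchanged untreated and ADR arrays within lymphomas, of 8192 possible. Only the real split, 1 of 100, gave as many genes for the 2790 higher, the 2435 lower and the 598 and 335 that changed at least 2-fold. The highest other splits gave 5, 5, 1 and 1 genes, so the real split stood apart from the others drawn. The smallest share that 100 splits can show is 1 of 100. Exchanged splits also turn real changes into spread between lymphomas, which lowers their counts. They do not show the counts of data without any effect.

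The mean of the SASP list was higher after ADR in all 14 lymphomas, with 25 of 38 members past the threshold and a list adjusted p of 0.148 with an estimated correlation. RNA of feeder fibroblasts may account for part of the rise: the SASP change followed the fibroblast change at r = 0.823. The fitted SASP change at no fibroblast change was 0.56 ± 0.15 (SE), but few lymphomas lay near that point. This value does not decide whether feeder RNA is the whole of the rise. The fibroblast list was used as a stand-in for the amount of feeder RNA, which was not itself measured. Feeder cells that raise SASP genes after ADR could leave such a value without a change of that list. For macrophage RNA, r = 0.249 with the macrophage change (permutation p = 0.400) leaves a part in the rise open. With both lists in the fit, the SASP change at no change of either was 0.32 ± 0.19, with slopes of 0.33 ± 0.06 and 0.18 ± 0.10, so RNA of both cell types together cannot be told apart from secretion by senescent lymphoma cells. Senescence of the lymphoma cells stays open as an untested biological explanation, and so does a response of the feeder cells themselves to ADR.

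The mean of the G2/M list was lower after ADR in all 14 lymphomas, at a list adjusted p of 0.150 with an estimated correlation. A lower share of lymphoma cells in the ADR arrays as the whole of the fall is argued against, since the G2/M list fell further than the mature B cell list in 13 of 14 lymphomas and its fitted change at no fibroblast change was -2.12 ± 0.40. Loss of cycling within the lymphoma cells stays open, as does a smaller contribution of the cell share.

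The mean of the mature B cell list was lower in 11 of 14 lymphomas, at a list adjusted p of 0.429 with an estimated correlation, and went down as the fibroblast list went up (r = -0.830), with a fitted change of 0.27 ± 0.16 at no fibroblast change. A lower share of lymphoma cells in the ADR arrays is a candidate explanation for this fall. Loss of B cell identity within the lymphoma cells was not tested apart from it, and Cd22 kept an adjusted p of 0.0225 in the covariate fit.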

How the results depend on the processing

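Fits with the fibroblast change as a covariate, without lymphomas 403 and 5560, and the sign-flip tests were chosen only after the result was seen. Without the replicate block 1933 genes were higher and 1723 lower, of which 1915 and 1702 were also called with it, 20 of 115 called named genes were lost and no list call changed. Other choices of block, probe set, filter, normalization, variance model and weights gave 2450 to 2913 higher and 2357 to 2592 lower genes, and leaving out each lymphoma gave 2419 (without 3769) to 2862 (without 2949) higher and 2082 to 2572 lower. The median of all genes moved by at most 0.02. Bcl2 read 0.19 by the probe set with the largest variance. The granulocyte list was called by camera without the dimmest 40% of genes (adjusted p = 0.0357). Its median was then 2.08, against 0.04 with all measured members. That filter used the mean over untreated and ADR arrays, so members that rose after ADR were more easily kept. The granulocyte call there is thus not independent support for a rise. With an estimated correlation none of the 21 list calls held: adjusted p was 0.148 for S phase, SASP, lysosome, repair and chromatin, 0.150 for G2/M, 0.152 for autophagy, TCA cycle, oxidative phosphorylation, NRF2, immune ligands and macrophage, and 0.159 for fibroblast. It was 0.189 for NF-kB, interferon and cholesterol, 0.228 for p53 targets, 0.234 for handling stress, 0.429 for the unfolded protein response and mature B cell lists and 0.585 for ribosome biogenesis; this setting allows for members that move together. By directional fry, adjusted p was 0.117 for ribosome biogenesis, and BCL2 family (0.00463), stem cell (7.50e-05), granulocyte (6.65e-04) and endothelial (0.0213) lists passed. Mixed fry, which also counts members that go opposite ways, passed CDK inhibitors (1.46e-04), MHC class I (0.00419), proteasome (4.66e-05), glycolysis (1.56e-08), BCL2 family (9.88e-09), stem cell (1.36e-08), pre-B (6.45e-06), plasma cell (0.0460), granulocyte (5.50e-04), T and NK cell (0.00155) and endothelial (2.80e-07) lists. By exact sign-flip, adjusted p was 0.123 for ribosome biogenesis, 0.0188 for BCL2 family and 4.27e-04 for stem cell and granulocyte lists. It was 0.0163 for T and NK cell and 0.0202 for endothelial lists. Fry and the sign-flip test ask only whether a list changed at all, and 28.7% of genes tested passed the threshold. A pass by them is thus weak support for a change particular to a list. Within the earlier 11 lymphomas the proteasome list passed (adjusted p = 0.00477) and 1 relation of the G2/M list passed, that with ribosome biogenesis. Leaving out each lymphoma, the proteasome list ranged from 0.00728 (without 5043) to 0.152 (without 2581). With the other 3 lymphomas alone, 1 gene was higher and 0 lower, 1 and 0 of them by at least 2-fold, as fewer samples were tested. There Prpf38a was at 0.065, Psmc6 at 0.0093, Myb at 0.13, Sdc1 at -0.079 and Thy1 at -0.024, and adjusted p was 0.232 for the unfolded protein response, 3.14e-05 for glycolysis, 0.917 for ribosome biogenesis, 0.0478 for stem cell, 0.171 for mature B cell and 0.0497 for endothelial lists. With the fibroblast covariate 1032 genes were higher and 878 lower, of which 564 and 612 were also called without it, and 217 rose at least 2-fold. Reversed genes there were Myc (0.16), H2-D1 (-0.056), Map1lc3a (-0.25), Dram1 (-0.25), Ddit3 (-0.076), Eno2 (-0.58), Nop58 (0.29), Ppat (0.087), Nqo1 (-0.52), Cd34 (-0.26), Bach2 (0.65), Myb (0.85), Sdc1 (-0.38), Thy1 (-1.01) and Fos (-0.26). Adjusted p was 0.112 for NF-kB and for immune ligands, 0.431 for autophagy, 0.0714 for the unfolded protein response, whose median went from 0.16 to 0.21, 3.19e-05 for glycolysis and 0.227 for NRF2, and the median changed sign for ribosome biogenesis (6.55e-09), mature B cell (0.184), fibroblast (0.313) and handling stress (0.661) lists. The mean of the fibroblast list was itself the covariate, so the entry of that list was fixed by construction. Without 403 and 5560 the 21 called lists were called and the other 14 were not, and 11 called named genes were lost. The count of genes that differ between the 11 and the 3 lymphomas was 0 without the dimmest 40% of genes. That filter removed Slc47a1 itself, so its difference was not tested there. The count was 0 to 1 when each lymphoma was left out. Except where the number of samples or the construction of a test is named, the cause was not tested. Signal over background limits genes near the low end of the scale.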

Other observations

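Values here were noticed after the data were seen, except the Y-linked genes, which were set beforehand for the pairing check. The test of p53-target levels was chosen only after the result was seen.

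The change of the p53-target list ran from -0.41 in lymphoma 2949, -0.07 in 6054 and 0.10 in 7050 to 1.27 in 1570. A hypothesis was that lymphomas with a small change start from a higher level and end closer together. The mean of both levels was set against the change, and r was -0.0712 (permutation p = 0.809; rho = -0.09, permutation p = 0.773), with -0.14 without lymphomas 2581 and 7050 and -0.24 within the earlier 11. List levels had an SD of 0.32 in untreated and 0.30 in ADR cultures, and ranged from 7.63 to 8.77 and from 8.09 to 9.13. This test turns on whether the spreads of both groups differ. It does not show whether lymphomas with a small change start higher. The untreated level alone was not tested against the change, of which it is a part. The hypothesis stays undecided.

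Lymphomas differed in B-lineage genes. Cd5, a surface protein of B-1 and T cells, was at 9.81 to 10.6 in untreated 2949, 5043, 5766, 6054 and 7050 and at 3.99 to 7.19 in the other 9. The immunoglobulin joining chain gene Jchain was at 3.40 to 4.72 in the first 5, and at 13.4 in 9584, 12.6 in 3594, 12.2 in 9583 and 12.1 in 1570. The immediate early gene Egr1 was at 11.6 in untreated 2949 and 4.33 in untreated 2581, and at 8.67 and 9.22 after ADR.

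Some early B cell genes changed strongly in part of the lymphomas. Dntt, which adds nucleotides at antigen receptor joints, went from 9.92 to 6.37 in 3594, from 10.4 to 6.78 in 3769 and from 9.09 to 4.82 in 9584. The surrogate light chain genes Igll1 and Vpreb1 went from 9.71 to 5.61 and from 9.45 to 4.42 in 5560. In 5766 they went from 8.47 to 6.41 and from 7.68 to 5.35, and in 6054 Vpreb1 went from 6.28 to 4.59. They stood at 10.4 and 8.81 after ADR in 5043. Cdkn2a was at 7.30 untreated and 7.64 after ADR in 403, and at 5.98 and 5.75 in 3594.

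The Y-linked Eif2s3y went from 4.74 to 8.61 in lymphoma 9584 and from 3.03 to 4.94 in 5560, where Xist was low in both arrays. The Y-linked Kdm5d stood at 7.17 and 7.20 in 9584, and went from 2.47 to 3.78 in 5560. In 3769 and 7050, with high Xist, Eif2s3y went from 2.72 to 4.35 and from 2.94 to 4.23, while Kdm5d went from 2.42 to 3.14 and from 5.21 to 3.96. The Y-linked genes thus moved apart in 9584 and 7050. The fibroblast list mean rose beside Eif2s3y, from 5.20 to 9.14 in 5560, 4.94 to 7.61 in 3769 and 4.59 to 6.78 in 7050. In 2581 it went from 4.81 to 7.43, with Eif2s3y from 2.98 to 3.76. In 1467 it went from 5.08 to 5.01, with Eif2s3y from 3.02 to 2.88. In 9584 it went from 5.11 to 6.08. Whether feeder RNA adds to the Y-linked signal was not tested. Whether the arrays of these pairs hold cells of 1 lymphoma alone was not settled here. Lymphoma 5043 had Xist at 11.3 and Eif2s3y at 5.47 when untreated.

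In the fit with the fibroblast change as a covariate, the largest values at no fibroblast change were those of myeloid genes: Acod1 (3.65 ± 0.40), Ms4a6d (3.49), Clec4a3 (3.26), Lyz2 (3.00) and Clec4d (2.93).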
